A study of Mus musculus with 2 samples.

How the data were processed

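Single-cell RNA was measured with the 10x 3' V2 kit in 2 libraries, 1 from lymph node and 1 from spleen, of sorted CD4+ CD25+ cells, YFP-positive and YFP-negative together. The deposited UMI counts per gene and barcode were made with Cell Ranger 3.0.1 on build mm10, per the submitters' processing notes. No deposited barcode holds fewer than 500 UMIs, so a cell call or filter at that depth came before deposit. The gene table lists Ensembl genes and 3 added features, EYFP, ICRE and CRE. Gene positions come from GENCODE M21 on GRCm38. The YFP status of a cell and the animal it came from are not given in the sources used here.

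Groups, comparisons, gene lists, cell type markers, the rule for named genes and most processing alternatives were fixed before the data were examined. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left out 259 lymph node and 297 spleen barcodes. Scrublet, run through scanpy 1.11.5, called 0 lymph node doublets and 1 spleen doublet, which was removed. At this number of cells such a caller has not worked, so doublets remain in the data. An added alternative left out the highest 6% of scores in each library.

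Both libraries were clustered together in Python 3.11.15 (Leiden resolution 1, 2000 variable genes, 30 principal components, 15 neighbours; igraph 0.11.9, scikit-learn 1.9.0). Pathway genes, T cell receptor, immunoglobulin, mitochondrial, ribosomal and haemoglobin genes, Xist, the added features, Myc and genes over 1.5-fold different between the libraries were left out of the clustering genes. A first version of the clustering left T cell receptor gamma constant genes in by error. It was corrected to the fixed design after its results had been seen, and its values stand among the alternatives. Clusters were named when at least 3 fixed markers were among their top 25 genes by fold. Clusters with resting T cell markers were called resting Treg-like where the lower bound of the summed Foxp3 and ICRE level passed the highest such level among B-like, CD8 T-like and NK or innate lymphoid-like clusters (68.6 CPM), a threshold set after seeing the data. It keeps cluster 7, at 70.0 CPM with a lower bound of 57.8, as resting T-like (2.99% of lymph node and 4.91% of spleen cells) and leaves cluster 11 unnamed (1.87% and 2.11%).

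For expression, counts were summed over cells and scaled to CPM. With 1 library per tissue no test was made, and no p-value, standard error or count of changed genes was taken from cells. Counts of genes over 1.5-fold were planned, and they are not reported. CPM has exact Poisson 95% intervals, shares exact binomial (Clopper-Pearson) intervals and ratios exact conditional intervals, all for counting error only (scipy 1.17.1). A list median has a binomial 95% interval over its member genes, which reflects their spread and takes them as independent. A count of 0 was set to a floor of 3 counts for its ratio. For gene lists, members with a mean of at least 20 CPM gave a median log2 ratio, with its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. The 14 pathway lists were Myc targets, ribosomal proteins, translation factors, glycolysis, oxidative phosphorylation, amino acid transport, one carbon and nucleotide synthesis, sterol synthesis, interferon response, immediate early and T cell receptor response, heat shock, mitochondrially encoded genes, DNA replication and mitosis. The 4 function lists were lymph node homing, tissue homing, Treg suppressor effectors and T helper cytokines.

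Named genes between tissues had at least 50 CPM in 1 library and 100 UMIs over both, and were the 12 on each side with the ratio bound farthest from 1. Up to 4 members per list were named by size of ratio, in the within-library contrasts among those with the same sign in both libraries. Myc, Foxp3, Il2ra, Ikzf2, Ccr7, Mki67 and the added features were always included. Some genes that the rule names are not reported here.

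To compare shares of cells with a UMI, and ICRE-positive with ICRE-negative cells, each cell was thinned to 1200 UMIs, which left out 252 lymph node and 525 spleen cells below that depth. A cell with at least 1 ICRE UMI was called positive. The share of ICRE among ICRE and Foxp3 UMIs was chosen as a measure after the data were seen. Alternatives covered cell filters, doublets, clustering genes and resolution, scaling, weights of cells, list minimums, thinning and the ICRE call.

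The scripts were tested on simulated data with 200 altered genes. The intervals held the true ratio for 95.1% of 4987 genes between tissues, 96.03% of 4967 in the lymph node ICRE contrast and 96.4% of 4984 in the spleen one. At a true 1.5-fold difference, 100% of altered genes were recovered between tissues, and 50.7% and 70.1% in the lymph node and spleen ICRE contrasts. The simulated totals were those of all kept cells, with 264 and 359 ICRE-positive cells. The reported ICRE contrasts hold 146 and 197 such cells, and the tissue contrast likewise holds fewer UMIs than were simulated. Recovery in the reported contrasts may therefore be lower. Counts were drawn from the Poisson model that the intervals assume, so other variation was not tested.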

Results

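Regulatory T (Treg) cells restrain immune responses and depend on the transcription factor Foxp3. The study profiled single CD4+ CD25+ T cells, the surface phenotype that enriches Treg cells, from healthy female mice in which both copies of Myc are floxed and 1 copy of the X-linked Foxp3 gene carries Cre. Each female cell silences 1 X chromosome, so Treg cells that use the Cre allele live beside Treg cells that use the wild-type allele in the same animal. Cells with and without the YFP reporter were sorted and loaded together, in a ratio the labels do not state, into 1 droplet lane per tissue. There are 2 libraries, 1 from lymph node and 1 from spleen, so there is no replicate and no test between tissues. Every interval given is a 95% interval of counting error only, except for list medians. Their intervals reflect the spread among the member genes of a list.

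The lymph node library held 5079 barcodes with 13324306 unique molecular identifiers (UMIs), and the spleen library held 6840 barcodes with 16868549 UMIs. After filtering, 4820 lymph node cells with a median of 2031 UMIs and 6542 spleen cells with a median of 1935 UMIs entered the comparisons.

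Myc, the floxed gene, encodes a transcription factor that drives growth and ribosome production. It was present at 30.7 CPM, UMIs of a gene scaled to the library total (interval 27.8 to 33.8, 409 UMIs), in the lymph node library and at 37.6 CPM (interval 34.7 to 40.6, 634 UMIs) in the spleen library. Myc (ENSMUSG00000022346) lies on chromosome 15 from 61985391 to 61990374 on the plus strand of GRCm38. The labels do not say which Myc exons are floxed, so it is not known whether the 3' tag lies in the deleted part, and a Myc UMI does not tell a deleted from an intact cell. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand) was at 110.5 CPM (interval 105.0 to 116.3) in lymph node and 108.1 CPM (interval 103.2 to 113.2) in spleen.

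Of the 3 sequences added to the gene table, named EYFP, ICRE and CRE, only ICRE gave a usable signal. ICRE had 442 UMIs in 383 barcodes of the lymph node library and 651 UMIs in 558 barcodes of the spleen library. EYFP had 0 UMIs in lymph node and 2 in spleen, and CRE had 0 in both. At 0 UMIs the exact upper bound of the share of barcodes with a captured UMI is 0.0726% in lymph node and 0.0539% in spleen, which does not bound the share of cells that express the feature. The ICRE sequence is not given in the sources used here, so reading ICRE as a mark of the Cre allele is an assumption. In Treg-like states thinned to 1200 UMIs per cell, ICRE and Foxp3 shared 3 of 2921 lymph node cells and 7 of 3312 spleen cells, where independent capture within clusters would give 10.2 and 13.8. At 1200 UMIs per cell, 5.78% of lymph node cells and 5.97% of spleen cells had an ICRE UMI, against 7.86% and 8.39% without thinning. The mixture of YFP-positive and YFP-negative cells can set these shares. B-like cells, which should lack Foxp3 transcripts, had ICRE in 1.94% of 103 lymph node cells and in 0 of 100 spleen cells at that depth, where 7.77% and 1.92% had it without thinning. Their median depth was 3056 and 2266 UMIs.

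Clustering gave 14 clusters, and the fixed markers named most of them. Treg-like cells made up 33.2% of lymph node cells (interval 31.9 to 34.6) and 25.2% of spleen cells (interval 24.2 to 26.3). Resting Treg-like cells, marked by genes of circulating T cells such as Ly6c1 and Satb1, were 26.2% (interval 24.9 to 27.4) and 25.9% (interval 24.8 to 27.0). Effector Treg-like cells, marked by S100a4, Klrg1 and Gzmb, were 5.41% (interval 4.79 to 6.09) and 5.56% (interval 5.02 to 6.15). Cycling cells were 1.64% and 1.39%, and interferon-response T-like cells were 9.23% and 14.0%. Smaller classes were resting T-like (2.99% and 4.91%), B-like (2.14% and 1.59%), CD8 T-like (0.685% and 0.673%) and NK or innate lymphoid-like (0.560% and 0.504%). A further 17.9% of lymph node cells and 20.3% of spleen cells stayed unnamed. The sort on CD4 and CD25 sets these shares, and they moved with the clustering: the spleen share of resting Treg-like cells ranged from 19.1% to 58.5% over 10 alternatives, and with each library clustered on its own the Treg-like shares were 20% in lymph node and 26.8% in spleen, in the opposite order. The make-up of the Treg-like class differed between the 2 tissues, with cluster 0 the larger in lymph node and both its clusters near equal in spleen. Cluster 0, led by Serpina3g, Cst7 and Nrp1, held 1237 of the lymph node cells and 810 of the spleen cells, and cluster 4, led by Lrrc32, Socs1 and Il2ra, held 364 and 840.

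The design asks how Treg cells of the Cre allele compare with Treg cells of the wild-type allele in the same mouse. ICRE transcripts were nearly absent from effector Treg-like cells and common in resting ones. ICRE made up 1.19% (interval 0.144 to 4.23) of the 168 ICRE and Foxp3 UMIs of lymph node effector Treg-like cells and 0.576% (interval 0.0699 to 2.07) of 347 in spleen. In resting Treg-like cells the share was 54.1% (interval 47.8 to 60.2) of 259 UMIs and 50.3% (interval 44.6 to 56.0) of 310. That class was drawn with a threshold on the sum of ICRE and Foxp3, which cluster 5 passes only with its ICRE. Over all clusters named resting by markers alone, with no such threshold, the share was 50.8% (interval 45.0 to 56.7) of 295 UMIs and 46.0% (interval 41.0 to 51.1) of 389. Cycling cells had 0 ICRE among 64 such UMIs in lymph node (interval 0% to 5.60%) and 1.69% (interval 0.206 to 5.99) of 118 in spleen.

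The Treg-like class was split in the main clustering, and values of single clusters were not followed over the alternatives. The ICRE share of the whole class was 9.59% in lymph node and 23.4% in spleen. Over 10 alternatives it ranged from 6.43% to 36.7% and from 10.9% to 33.5%. Cluster 0 had an ICRE share of 1.41% in lymph node (interval 0.676 to 2.57) and 2.78% in spleen (interval 1.49 to 4.71), whereas in cluster 4 ICRE gave 72 of 144 such UMIs in lymph node (interval 41.6% to 58.4%) and 54.5% in spleen (interval 48.8 to 60.2). Among resting Treg-like cells, cluster 5 reached 70.7% and 55.5%, and cluster 1 had 36.5% and 33.8%. The interferon-response T-like cells were at 25.9% (interval 19.4 to 33.4) and 23.4% (interval 18.9 to 28.4), and resting T-like cells at 27.8% (interval 14.2 to 45.2) and 29.1% (interval 19.4 to 40.4). B-like cells, which should lack both transcripts, were at 28.6% (interval 13.2 to 48.7) of 28 UMIs and 14.3% (interval 1.78 to 42.8) of 14. The unnamed cluster 6, led by Gsta4 and Gpr83, had 59.3% and 51.5%, and the unnamed cluster 2, led by Tnfrsf9 and Ccl1, had 30.3% and 31.6%. By CPM, ICRE was at 63.6 (interval 53.5 to 75.0) in lymph node resting Treg-like cells and at 2.35 (interval 0.284 to 8.47) in effector Treg-like cells. The spleen values were 55.2 (interval 46.9 to 64.6) and 1.66 (interval 0.201 to 6.003). The share compares transcripts of different capture, so it is not a share of cells. The effector value stayed between 0.521% and 2.36% in lymph node and between 0.291% and 1.08% in spleen under the 9 alternatives that named that class.

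**Figure D1:**
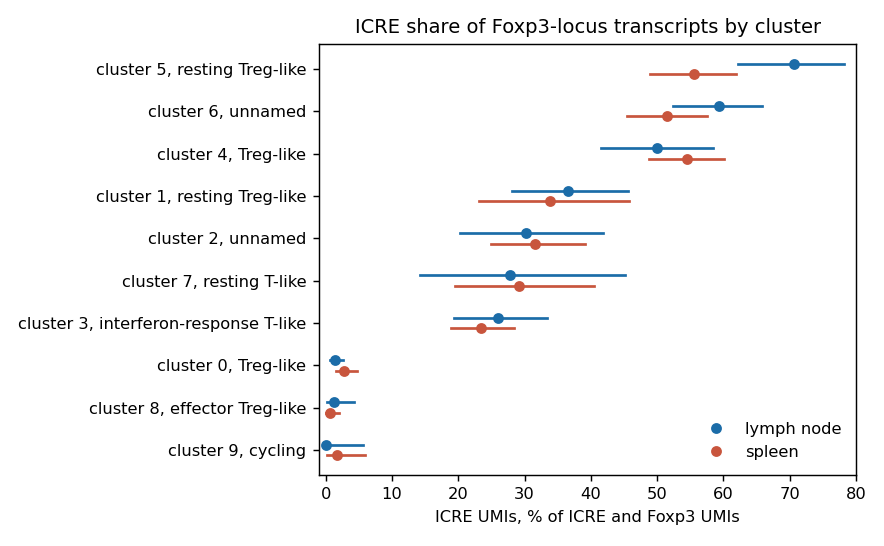
ICRE UMIs as a percentage of ICRE and Foxp3 UMIs (horizontal axis) in each cluster with at least 30 such UMIs in each library (vertical axis), for lymph node and spleen; points are shares and bars exact binomial 95% intervals of counting error. Clusters 0, 8 and 9 lie below 3% in both tissues, and clusters 4, 5 and 6 lie at 50% or above.

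Over all Treg-like states, cells with an ICRE UMI had lower ribosomal protein transcripts than cells without one, in both tissues, a difference that shrank when cells were matched on UMIs. At 1200 UMIs per cell there were 146 ICRE-positive and 2775 ICRE-negative cells in lymph node and 197 and 3115 in spleen. The unnamed cluster 6, with ICRE at 112 and 94.7 CPM, held 72 and 77 further positive cells that did not enter. Of 76 ribosomal protein genes, 67 were lower in ICRE-positive cells in each tissue, with median log2 ratios of -0.15 and -0.16 and a percentile of 0 among 10000 matched random lists in both. Among them Rps12, a small-subunit protein, was 1.56-fold lower in lymph node (interval 1.36 to 1.81) and 1.52-fold lower in spleen (interval 1.34 to 1.74). Rplp0, of the ribosomal stalk, was 1.42-fold lower (interval 1.31 to 1.54) and 1.39-fold lower (interval 1.29 to 1.49), and Rps2 was 1.35-fold and 1.40-fold lower. Translation factors were lower as well, in 20 of 27 members in lymph node (median -0.24, percentile 0.025) and 15 of 27 in spleen (median -0.11, percentile 0.98). Eef2, the elongation factor that moves the ribosome along the message, was 1.46-fold lower (interval 1.26 to 1.71) and 1.29-fold lower (interval 1.15 to 1.46). Eef1a1, which delivers aminoacyl-tRNA, was 1.36-fold and 1.24-fold lower. The median of all genes in these contrasts was 0.11 in lymph node and 0.088 in spleen. ICRE-positive cells had held fewer UMIs before thinning, with medians of 1517.5 against 2085 in lymph node and 1548 against 1900 in spleen. With ICRE-negative cells weighted to the UMIs per cell of the positive cells, a choice made after seeing the data, the ribosomal protein medians shrank to -0.049 (interval -0.075 to -0.027) and -0.072 (interval -0.095 to -0.047), and those of translation factors to -0.11 and -0.082. Rps12 then had log2 ratios of -0.24 and -0.31, against -0.64 and -0.61 without weights.

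Resting Treg-like cells taken alone gave the like picture, with 71 of 76 ribosomal protein genes lower in lymph node (median -0.18) and 74 of 76 in spleen (median -0.19). Myc targets as a list had no common direction in ICRE-positive cells: 26 of 43 were higher in lymph node (median 0.15, percentile 69.6) and 20 of 40 in spleen (median -0.0049, percentile 13.02). Pa2g4, a growth-linked nucleolar protein, was at 45.7 against 85.3 CPM in lymph node and 63.5 against 86.7 CPM in spleen, with intervals that include equality. Mcm6 was 1.69-fold and 1.38-fold lower, whereas Mrto4 was 2.02-fold and 1.21-fold higher and Mcm2 1.58-fold and 1.45-fold higher. Their intervals include equality as well. Myc itself had 1 UMI in lymph node and 3 UMIs in spleen among ICRE-positive cells after thinning, 4.47-fold lower (interval 0.781 to 179) and 2.76-fold lower (interval 0.924 to 13.6) than in ICRE-negative cells. Without thinning it was 3.43-fold lower (interval 1.16 to 16.8) and 2.11-fold lower (interval 1.13 to 4.45). Within classes the unthinned intervals include equality, at 2.67-fold (interval 0.728 to 22.2) and 1.84-fold lower (interval 0.952 to 4.09) in Treg-like cells and 2.41-fold (interval 0.391 to 99.2) and 4.26-fold lower (interval 0.733 to 171) in resting cells.

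Klf2 and Il2ra were higher in ICRE-positive Treg-like cells. The tissue homing and suppressor lists had lower medians, of which only tissue homing in spleen stayed lower under weighting to clusters. Klf2, Il2ra, Lrrc32, Icos, Cxcr3, Itgb1, Ikzf2 and Foxp3 are all also markers used to name the clusters. Klf2, a transcription factor that keeps T cells recirculating, was 1.93-fold higher in lymph node (interval 1.73 to 2.15) and 1.55-fold higher in spleen (interval 1.40 to 1.70). Il2ra, the CD25 chain of the interleukin-2 receptor, was 2.05-fold (interval 1.53 to 2.70) and 1.74-fold higher (interval 1.38 to 2.17), and Rgs1, a regulator of chemokine receptor signalling in the tissue homing list, was 1.84-fold and 1.62-fold higher. Lrrc32, a suppressor list gene that holds latent TGF-beta at the cell surface, was 2.05-fold higher (interval 1.29 to 3.14) and 1.49-fold higher (interval 0.956 to 2.23). Icos, a costimulatory receptor of effector Treg cells, was at 2 UMIs in lymph node, 10.3-fold lower (interval 2.83 to 85.2), and was 2.03-fold lower in spleen (interval 1.36 to 3.19). Cxcr3, a receptor for interferon-induced chemokines, was 3.08-fold lower (interval 1.40 to 8.44) and 4.27-fold lower (interval 1.16 to 35.6, 2 UMIs). Itgb1, an integrin chain, was 3.53-fold and 3.31-fold lower, and Ikzf2, the Treg transcription factor Helios, was 1.45-fold and 1.42-fold lower. Foxp3 was 7.997-fold lower (interval 2.72 to 38.9, 3 UMIs) and 3.85-fold lower (interval 1.85 to 9.63). If ICRE marks the Cre allele, calling cells by ICRE selects against Foxp3 transcripts of the other allele. So these ratios do not show a loss of Foxp3 expression.

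The tissue homing list had medians of -0.56 (7 of 9 members lower, percentile 0.060) in lymph node and -0.95 (9 of 11 lower, percentile 0) in spleen, and the suppressor effector list -0.50 (percentile 0.12) and -0.24 (percentile 1.10), with 5 of 8 members lower in each. With ICRE-negative cells weighted to the clusters of the positive cells, a choice made after seeing the data, these became 0.51 and -0.15 for tissue homing and 0.19 and 0.37 for suppressor effectors. Under that weighting the ribosomal protein median was -0.15 in lymph node and -0.18 in spleen, and with weights for clusters and UMIs per cell together it was -0.067 and -0.095. Cxcr3 in lymph node went to a log2 ratio of 0.78, Icos in spleen to 0.69 and Ikzf2 to 0.054 and -0.026, while Il2ra fell from 1.03 and 0.80 to 0.47 and 0.33 and Klf2 from 0.95 and 0.63 to 0.27 and 0.28. Lymph node homing genes had medians of 0.22 and 0.29 (percentiles 84.2 and 98.3) and sterol synthesis genes 0.79 and 0.21 (percentiles 99.98 and 67.5). Mitochondrially encoded genes were lower in 10 of 12 members in each tissue (medians -0.17 and -0.25). Reporter-negative cells include Cre-allele cells whose ICRE was not captured, and no library comes from mice with the Cre allele and unfloxed Myc. Whether Myc was deleted in every Cre-allele cell was not measured.

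**Figure D2:**
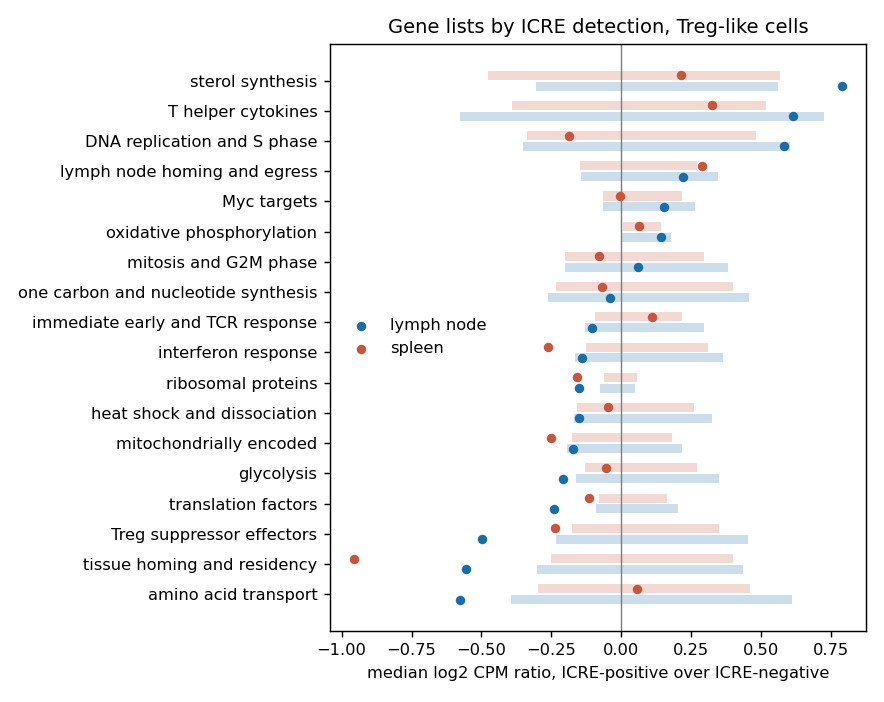
Median log2 CPM ratio of each gene list in ICRE-positive over ICRE-negative Treg-like cells (horizontal axis) at 1200 UMIs per cell, for lymph node and spleen; shaded bars span the central 95% of medians of 10000 matched random lists. The ribosomal protein points, at -0.15 and -0.16, lie left of their bars in both tissues, and tissue homing reaches -0.95 in spleen.

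A further comparison set effector against resting Treg-like cells within each library, using pathway genes that were kept out of the clustering. ICRE made up 1.19% and 0.576% of ICRE and Foxp3 UMIs in effector cells, against 54.1% and 50.3% in resting cells. If ICRE marks the Cre allele, state and allele cannot be told apart in this contrast. Cluster 5 holds 827 of the 1262 resting Treg-like cells in lymph node and 1366 of the 1694 in spleen, and its Foxp3 (29.7 and 48.7 CPM) and Ikzf2 (370 and 266 CPM) were no higher than in B-like cells beyond counting error (Foxp3 45.7 and 39.8 CPM, Ikzf2 389 and 299 CPM). So it is not established that all resting cells, here and in the ICRE contrast, are Treg cells. Effector Treg-like cells had lower ribosomal protein transcripts and higher transcripts of glycolysis and sterol synthesis. Ribosomal protein genes were lower in 68 of 76 members in lymph node (median -0.47, percentile 0) and 69 of 76 in spleen (median -0.45, percentile 0), with Rps29 2.40-fold lower (interval 2.32 to 2.49) and 2.31-fold lower (interval 2.24 to 2.39) and Rps27 2.19-fold and 2.07-fold lower. Glycolysis genes were higher in 11 of 14 members (median 0.69, percentile 99.7) and 13 of 15 (median 0.58, percentile 99.3). Tpi1, triosephosphate isomerase, was 2.92-fold higher (interval 1.99 to 4.31) and 3.14-fold higher (interval 2.32 to 4.28), and Pgk1, an ATP-producing enzyme, was 2.06-fold and 1.90-fold higher, whereas Ldhb, a lactate dehydrogenase, was 2.01-fold and 2.25-fold lower. The median of all genes in these contrasts was 0.16 in lymph node and 0.17 in spleen.

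Sterol synthesis genes were higher in effector cells in 14 of 15 members in lymph node (median 0.68) and 9 of 9 in spleen (median 0.81). Mvd, of the mevalonate pathway, was 4.24-fold (interval 2.60 to 7.05) and 3.56-fold higher (interval 2.18 to 5.91). Interferon response genes were higher in 16 of 20 (median 0.57) and 18 of 22 (median 0.73), with the antiviral sensor Oas1a 4.95-fold and 8.92-fold higher. Cells led by interferon genes such as Ifit1 form the separate interferon-response T-like class, which also has the resting markers Ly6c1 and Igfbp4 among its leading genes. They are outside the resting class, so the naming of classes can itself lower interferon transcripts in that comparator. Mitosis genes were higher in 9 of 12 (median 1.45) and in 5 of 8 (median 0.80), where the other 3 had intervals wholly below equality, with Cks2, a cyclin-dependent kinase subunit, 4.25-fold and 7.85-fold higher. Mki67, a marker of cycling cells, had 0 UMIs in lymph node resting cells, so it has only a lower bound of 13.4-fold higher in effector cells there, and it was 20.4-fold higher in spleen (interval 6.24 to 105). Among Myc targets Odc1, the first enzyme of polyamine synthesis, was 2.65-fold and 3.49-fold higher, and Nop56, a nucleolar protein, was 2.55-fold and 1.69-fold lower. The list median was -0.067 in lymph node and 0.17 in spleen, and the spleen value turned negative under both other scalings and without the cells of highest doublet score.

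The other pathway lists, effector over resting, had these medians in lymph node and spleen: oxidative phosphorylation 0.17 and 0.21, translation factors 0.089 and 0.13, amino acid transport 0.29 and 0.41, and one carbon and nucleotide synthesis 0.19 and 0.097. Immediate early and T cell receptor response genes were at 0.12 and 0.33, heat shock genes at 0.034 and 0.10, mitochondrially encoded genes at 0.082 and -0.15, and DNA replication genes at -0.11 and 0.13.

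Myc levels differed by state. The states also differ in their ICRE share, so if ICRE marks the Cre allele, state and allele cannot be told apart here either. Myc was at 10.9 CPM (interval 6.98 to 16.2) in lymph node and 19.5 CPM (interval 14.7 to 25.3) in spleen resting Treg-like cells, and at 41.1 (interval 35.3 to 47.6) and 51.8 CPM (interval 45.1 to 59.2) in Treg-like cells. Effector Treg-like cells had 9.38 CPM (interval 4.05 to 18.5) in lymph node and 40.7 CPM (interval 30.1 to 53.8) in spleen. Effector over resting, Myc was 1.16-fold lower in lymph node (interval 0.505 to 2.99) and 2.09-fold higher in spleen (interval 1.39 to 3.13), but the spleen log2 ratio became -0.073 when cells needed at least 800 genes and at most 5% mitochondrial UMIs. At 1200 UMIs per cell a Myc UMI was found in 1.06% and 1.61% of resting Treg-like cells, 3.85% and 5.10% of Treg-like cells and 2.54% and 3.58% of effector Treg-like cells. Without thinning these shares were 1.74% and 2.54%, 7.62% and 9.33%, and 2.68% and 7.97%. NK or innate lymphoid-like cells had 1 Myc UMI in each library. Foxp3, at the same thinning, was found in 5.41% and 5.60% of resting, 18.5% and 12.9% of Treg-like and 19.9% and 29.6% of effector cells, and in 3.88% of lymph node and 4 of 100 spleen B-like cells, which should lack it. These were 7.61%, 7.85%, 33.2%, 24.7%, 44.1%, 56.3%, 10.7% and 9.62% without thinning.

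The design also sets lymph node against spleen. Treg-like states together held 3124 lymph node and 3708 spleen cells. Lymph node cells had higher transcripts of the NAD-consuming ecto-enzyme Art2b, of Gimap family GTPases of lymphocyte survival, and of Itga4, Cxcr3 and Gpr183, and spleen cells had higher transcripts of Apol9b, Igfbp4, Ctsw and Itgae. Art2b was 4.44-fold higher in lymph node (94.1 against 21.2 CPM, interval 3.75 to 5.28). Gimap7 was 2.52-fold higher (interval 2.33 to 2.73), with Gimap3 at 1.63-fold and Gimap4 and Gimap6 each at 1.57-fold. Itga4, an integrin chain of lymphocyte homing, was 2.62-fold higher (interval 2.30 to 2.996), Cxcr3 2.49-fold (interval 2.21 to 2.80), and Gpr183, an oxysterol receptor that positions lymphocytes, 2.21-fold (interval 1.92 to 2.56). Dtx1, a Notch-linked ubiquitin ligase, was 2.59-fold higher (interval 2.28 to 2.94), the chemokine Ccl5 1.91-fold, Cst7 1.78-fold and the bicarbonate carrier Slc4a7 1.77-fold.

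In spleen Apol9b was 5.11-fold higher (75.7 against 14.8 CPM, interval 4.17 to 6.33) and Igfbp4, which binds insulin-like growth factors, 4.195-fold higher (interval 3.58 to 4.94). Ctsw, a cathepsin of lymphocytes, was 3.35-fold higher (interval 2.85 to 3.97), and Itgae, the CD103 integrin chain that binds E-cadherin, 2.97-fold higher (interval 2.503 to 3.53). Socs2, an inhibitor of cytokine signalling, was 2.12-fold higher, Icos 2.02-fold, the cytokine Lta 1.89-fold, the actin-capping gene Capg 1.87-fold, Ecm1 and Skil each 1.73-fold, the chemokine receptor Ccr7 1.57-fold and Rgs1 1.53-fold. Il2ra was 1.42-fold higher in spleen (interval 1.32 to 1.54), Myc 1.37-fold (interval 1.15 to 1.64) and ICRE 1.37-fold (interval 1.15 to 1.63). Foxp3 (144 against 134 CPM), Ikzf2 (831 against 799) and Mki67 (5.84 against 6.37) were close in CPM over all Treg-like states. Within states Foxp3 had log2 ratios of 0.32 in Treg-like, -0.012 in resting and -0.56 in effector cells, and Ikzf2 0.42 in resting cells. The ICRE direction turned in resting Treg-like cells alone, with a log2 ratio of 0.20 for lymph node over spleen. Ccr7 had log2 ratios of -1.17 in Treg-like, -0.099 in resting and 0.45 in effector cells, and Cst7 turned to -0.38 in effector cells. Il2ra, Socs2, Lta and Rgs1 are among the 10 leading genes of cluster 4, and Cst7 and Cxcr3 among those of cluster 0, and the cell shares of these clusters differ between the tissues. Within cluster 4 ICRE (103.7 against 102.0 CPM in lymph node and spleen) and Il2ra (426 against 446) were close, and within cluster 0 Il2ra was at 130 against 174 CPM.

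**Figure D3:**
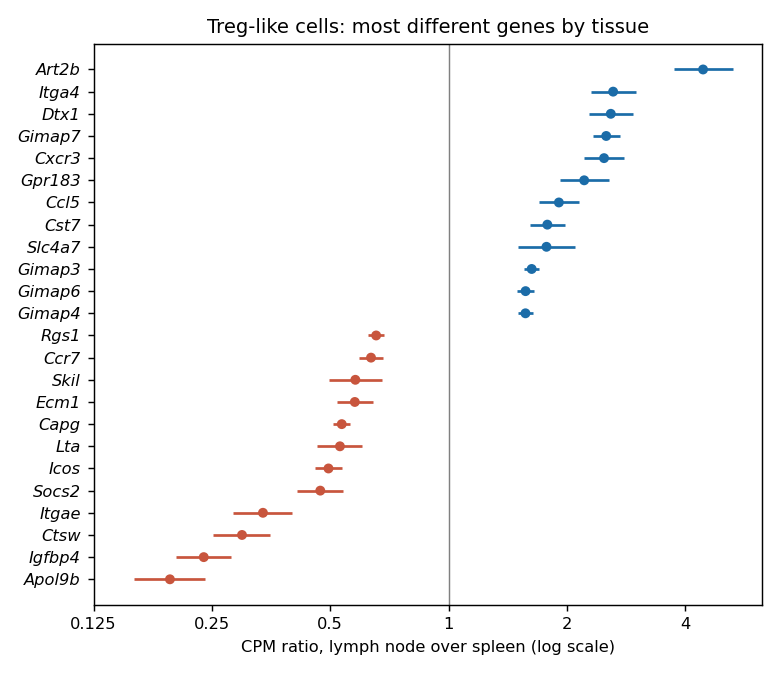
CPM ratio of lymph node over spleen (horizontal axis, log scale) for the 12 genes highest in each tissue over all Treg-like states (vertical axis); points are ratios and bars exact 95% intervals of counting error. Art2b lies farthest right at 4.44 and Apol9b farthest left at 0.196.

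Sterol synthesis genes stood out as a group, with 8 of 8 measured members higher in lymph node (median 0.27, percentile 99.97). Msmo1, a sterol oxidase, was 1.56-fold higher (interval 1.30 to 1.86), Fdps, which makes farnesyl diphosphate, 1.51-fold (interval 1.31 to 1.75) and Hmgcs1 1.32-fold. The median was 0.13 in Treg-like (6 of 7 members higher, percentile 88.7), 0.51 in resting (4 of 5) and 0.56 in effector cells (13 of 13). Outside these states it was 1.14 in interferon-response T-like cells (11 of 11 members higher, percentile 100), 0.48 in resting T-like cells (3 of 5 higher) and 0.24 in B-like cells (4 of 7 higher). The interferon-response T-like cells lie outside by marker name only. Their Foxp3 was at 118 and 116 CPM in lymph node and spleen, against 54.1 and 54.5 CPM in resting Treg-like cells. Myc targets were lower in lymph node in 37 of 42 members (median -0.17, percentile 0), with Ccnd2, a cyclin of G1 phase, 1.30-fold higher in spleen (interval 1.24 to 1.35) and the nucleolar genes Nip7 and Nolc1 1.27-fold and 1.26-fold. The medians were -0.13 in Treg-like, -0.12 in resting and -0.28 in effector cells. Outside these states they were -0.32 in resting T-like (32 of 41 lower), -0.15 in interferon-response T-like (34 of 42) and -0.015 in B-like cells (24 of 44).

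Interferon response genes were lower in lymph node in 16 of 19 members (median -0.19, percentile 0.020), with the antiviral Ifit1 1.75-fold higher in spleen (interval 1.46 to 2.09) and Usp18 1.49-fold. Immediate early and T cell receptor response genes were lower in 15 of 21 (median -0.10, percentile 1.84), with Egr1 1.49-fold, Nr4a1 1.46-fold and Cd69 1.41-fold higher in spleen. Within states their medians were -0.13 in Treg-like, -0.033 in resting (percentile 36.3) and -0.21 in effector cells. Heat shock and dissociation genes, which follow tissue handling, were lower as well, in 7 of 8 (median -0.13, percentile 2.03). Within Treg-like, resting and effector cells the percentiles of this list were 7.06, 17.8 and 8.72. Suppressor effectors were lower in 8 of 12 (median -0.16, percentile 0.85), although Lag3, an inhibitory receptor, and the cytokine chain Ebi3 were 1.38-fold and 1.45-fold higher in lymph node. The medians were -0.094 in Treg-like, 0.067 in resting and -0.48 in effector cells. Ribosomal protein genes were higher in 59 of 76 (median 0.042, percentile 99.3), with Rpl38 1.25-fold higher. Their median turned to -0.0023 at the coarser clustering resolution of 0.5. Oxidative phosphorylation genes were lower in 58 of 76 (median -0.078, percentile 0.66), with percentiles of 1.87 in Treg-like, 19.8 in resting and 15.9 in effector cells.

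Remaining lists had medians of -0.051 for translation factors, -0.025 for glycolysis, -0.039 for amino acid transport and -0.11 for one carbon and nucleotide synthesis. Mitochondrially encoded genes were at 0.018, mitosis at -0.042, lymph node homing at 0.019, tissue homing at -0.031 and T helper cytokines at 0.11. DNA replication genes were lower in 8 of 9 members, 2 with intervals wholly below equality (median -0.18, percentile 1.695). In effector cells 11 of 11 were lower (median -0.37), 0 of them with such an interval. Within states tissue homing was at -0.24 in Treg-like (percentile 0.050), -0.040 in resting and -0.25 in effector cells (percentile 0.40).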

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

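All tests of explanations given here were chosen after the result was seen. For other clusters and the comparator, the prediction was first written before its test was run, but outcomes under an earlier clustering had been seen by the time it was final.

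Haemoglobin transcripts, which belong to erythroid cells, gave 54889 UMIs in the lymph node library, in 27.0% of barcodes and with up to 9819 in 1 barcode, against 17 UMIs in spleen. Their genes were left out of clustering and of named genes. Those UMIs that lie in compared cells stayed in the CPM totals, and the genes could enter the random lists. ICRE gave 8 UMIs in lymph node B-like cells, a class outside the allele comparison, above the floor of 3 counts.

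ICRE was almost missing from effector Treg-like cells. Lower depth as a cause of few ICRE UMIs per cell is argued against. Effector cells held 1.86 times (lymph node) and 1.94 times (spleen) the median UMIs of resting cells. The ICRE share of ICRE and Foxp3 UMIs is not set by UMIs per cell, so this has no bearing on the share. Clustering on Foxp3 is argued against by the shares. Without that gene the effector share was 0.913% (interval 0.111 to 3.26) and 1.05% (interval 0.286 to 2.66). Both lie below 53.0% and 49.5%, the lower bounds in cells with resting markers. Free RNA would enter every droplet of a library alike. As the whole source of resting-cell ICRE it is argued against by lower bounds of 9.03 and 7.63 ICRE UMIs per 100 cells with resting markers, drawn with no threshold on ICRE, above the effector upper bounds of 2.77 and 1.98. B-like cells had 7.77 (interval 3.35 to 15.3) and 1.92 (interval 0.233 to 6.95) per 100 cells, so in lymph node the B-like interval includes the resting-cell level of 10.7. Loss of Myc may account for the effector shares of 1.19% and 0.576%. Without a library of Cre-allele cells with unfloxed Myc, it cannot be told apart from another effect of the Cre allele.

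Ribosomal protein transcripts were lower in ICRE-positive Treg-like cells. Fewer UMIs per cell before thinning fits part of the difference. With ICRE-negative cells weighted to the UMIs per cell of the positive ones, the medians went from -0.15 (interval -0.20 to -0.11) to -0.049 (interval -0.075 to -0.027) in lymph node and from -0.16 (interval -0.19 to -0.10) to -0.072 (interval -0.095 to -0.047) in spleen. With weights for clusters and UMIs together they were -0.067 (interval -0.089 to -0.050) and -0.095 (interval -0.12 to -0.065). In resting Treg-like cells, where positive and negative cells had closer UMIs (medians of 1492 against 1615 and 1479 against 1614), the unweighted ribosomal medians were -0.18 and -0.19, so how far UMIs per cell account for the difference stays open. Whether fewer UMIs reflect smaller cells or poorer capture was not tested. Their place in other clusters is argued against by weighted medians of -0.15 (interval -0.18 to -0.12) and -0.18 (interval -0.20 to -0.13). Against Foxp3-positive cells without ICRE the medians were -0.16 in both (intervals -0.21 to -0.10 and -0.20 to -0.093). This does not decide on a mixed comparator, because these cells were not weighted to the clusters or UMIs of the positive cells. Cluster 0 held 256 of 396 Foxp3-positive and 4 of 146 ICRE-positive cells in lymph node, and 140 of 378 and 8 of 197 in spleen. Loss of Myc and another effect of the Cre allele both stay open, untested.

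Sterol synthesis transcripts were higher in lymph node Treg-like cells, and by a larger median (1.14) in interferon-response T-like cells. The latter lie outside these states by marker name, yet held Foxp3 at 118 CPM in lymph node and 116 CPM in spleen. Another make-up of states as the whole cause is argued against by the medians within resting (0.51, 5 measured members) and effector cells (0.56, 13 members). Over all states the median was 0.27 (8 members). Treg-like cells had 0.13, inside the range of random lists (percentile 88.7). These medians cover different members, and cluster 5 held 827 of 1262 resting cells in lymph node and 1366 of 1694 in spleen. So a make-up of clusters within the resting and Treg-like states stays open. With the highest doublet scores left out the median was 0.35 (interval 0.038 to 0.66), but no value shows that these scores rank doublets, so doublets stay open. The tissue and any other difference between the libraries cannot be told apart at a median of 0.27, because each tissue has 1 library.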

How the results depend on the processing

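No paired analysis was possible because each tissue has 1 library. The alternatives with T cell receptor gamma genes kept, Foxp3 left out of clustering, the highest doublet scores left out, weighting to clusters, to UMIs per cell or to both, and Foxp3-positive comparators, and every alternative for the ICRE share, were chosen after the data were seen. Of the planned values 2558 stayed within the interval of the main value (for counts of genes, within 1.5-fold), 473 moved and 13 turned direction. Only log2 ratios with a main interval that excludes 0 could count as turned. Other changes of sign are among the values that stayed or moved. Of the added ones these numbers were 1863, 237 and 13. The ICRE share stayed at 0.521% to 2.36% (lymph node) and 0.291% to 1.08% (spleen) in effector Treg-like cells under 9 alternatives, and at 0% to 1.54% and 0.642% to 3.01% in cycling cells under 10. The ribosomal protein median stayed below 0 in the ICRE contrast (-0.18 to -0.049 and -0.22 to -0.072) and in effector over resting (-0.67 to -0.41 and -0.65 to -0.45). The sterol median between tissues stayed above 0, at 0.30 to 0.66 under 15 alternatives, all above the 0.27 reported. Class shares moved widely. The cause was not tested for any value below. At resolution 0.5 no effector class was named. Several alternatives gave no value: the sterol list at 50 CPM, Mki67 in resting cells alone and in the lymph node ICRE contrast with the Foxp3-positive comparator or the highest doublet scores left out, T helper cytokines under each weighting in lymph node, and Myc and other low genes in spleen with an ICRE call at 2 UMIs. Depth and the naming of clusters limit the ICRE contrast, which 146 and 197 positive cells entered. The unnamed cluster 6, with 72 and 77 positive cells, stayed outside it, although its Ikzf2 was at 1066 and 984 CPM.

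Where 2 values follow a result, the first is lymph node and the second spleen. Shares are in percent of cells or of ICRE and Foxp3 UMIs, and other values are log2 ratios. With tissue-different genes kept in clustering, values were lymph node over spleen Myc targets -0.21, lymph node over spleen Adsl 0.048, resting Treg-like share 28.8% and 24.5%, effector Treg-like share 6.39% (spleen), ICRE share in resting Treg-like 61.9% (node), ICRE share in Treg-like 12.5% (node). With the highest 6% of doublet scores left out, values were lymph node over spleen Myc targets -0.22, resting Treg-like share 33.3% and 34.3%, Treg-like share 36.7% and 29.8%, effector Treg-like share 7.61% and 6.65%, effector over resting Myc targets -0.18 (spleen), ICRE contrast Fos 0.16 (node). Under the same setting came ICRE share in Treg-like 15.8% and 29%. At resolution 0.5, values were lymph node over spleen ribosomal proteins -0.0023, lymph node over spleen Gzmb 0.59, resting Treg-like share 49.6% and 58.5%, Treg-like share 34.8% and 23.9%, cycling share 6.93% and 7.001%, ICRE share in Treg-like 6.43% and 10.9%. In resting Treg-like cells alone, values were lymph node over spleen ICRE 0.20, lymph node over spleen Dnajb1 0.12, lymph node over spleen Tnfsf11 -0.21. With no cell filter, values were resting Treg-like share 28.5% and 28.3%, effector Treg-like share 10.1% and 8.36%, Treg-like share 23.9% (spleen), effector over resting mt-Nd2 0.36 and 0.10, cells with a Myc UMI 2.8% (spleen), ICRE share in Treg-like 15.5% (node). With called doublets kept, values were resting Treg-like share 20.7% and 19.1%, Treg-like share 37.8% and 29.5%, ICRE share in Treg-like 18.3% and 32.2%. That setting adds only 1 spleen cell, so these moves show an unstable clustering and not the weight of doublets. At resolution 1.5, values were resting Treg-like share 28.4% and 29.7%, Treg-like share 35.3% and 27.3%, effector Treg-like share 6.24% (node), ICRE share in Treg-like 14.9% and 27.8%, ICRE share in resting Treg-like 37.3% (spleen). With each library clustered on its own, values were resting Treg-like share 19.2% and 22.9%, Treg-like share 20% and 26.8%, effector Treg-like share 4.63% and 6.82%, cycling share 2.3% (node), ICRE share in resting Treg-like 62.7% (node), ICRE share in Treg-like 36.7% and 28.3%. With Foxp3 left out of clustering, values were resting Treg-like share 24.4% and 22.9%, Treg-like share 28.7% and 20.5%, effector Treg-like share 6.41% and 6.18%, cycling share 2.63% and 2.75%, ICRE share in Treg-like 17.3% and 33.5%. With T cell receptor gamma genes kept in clustering, values were resting Treg-like share 35.9% and 38.6%, Treg-like share 38.2% and 27.7%, ICRE contrast ribosomal proteins -0.20 (spleen), ICRE share in resting Treg-like 45.3% and 38.7%, ICRE share in Treg-like 15.1% (node). With at least 800 genes and at most 5% mitochondrial UMIs, values were effector Treg-like share 8.81% and 8.45%, cycling share 2.32% and 2.1%, resting Treg-like share 32.2% (spleen), Treg-like share 19.8% (spleen), effector over resting Myc -0.073 (spleen), cells with a Myc UMI 4.43% and 5.71%. Under the same setting came cells with a Foxp3 UMI 17% and 15.6%, cells with a Mki67 UMI 1.2% (spleen), ICRE share in resting Treg-like 41.2% and 37.5%, ICRE share in Treg-like 18% (spleen). With totals without ribosomal and mitochondrial genes, values were effector over resting Myc targets -0.27 and -0.027, effector over resting ribosomal proteins -0.67 and -0.65, effector over resting oxidative phosphorylation -0.033 (node), effector over resting mt-Co2 -0.0070 (spleen). With median of ratios scaling, values were effector over resting ribosomal proteins -0.63 and -0.62, effector over resting Myc targets -0.00063 (spleen). With thinning to the 25th percentile, values were cells with a Myc UMI 3.56% and 4.74%, cells with a Foxp3 UMI 15.3% and 13.5%, cells with a Mki67 UMI 1.31% and 1.19%. Without thinning, values were cells with a Myc UMI 6.1% and 7.03%, cells with a Foxp3 UMI 20.9% and 18.9%, cells with a Mki67 UMI 2.37% and 1.96%. With cells weighted to the clusters of the positive cells, values were ICRE contrast Itgb1 0.35 (node), ICRE contrast Cxcr3 0.78 (node), ICRE contrast Nt5e 0.027 (node), ICRE contrast Ikzf2 0.054 (node), ICRE contrast Ccr2 2.93 (spleen), ICRE contrast Icos 0.69 (spleen). With cells weighted to both the clusters and the UMIs per cell of the positive cells, values were ICRE contrast Itgb1 0.33 (node), ICRE contrast Cxcr3 1.26 and 0.077, ICRE contrast ribosomal proteins -0.067 and -0.10, ICRE contrast Ccr2 3.05 (spleen), ICRE contrast Icos 0.63 (spleen). With cells weighted to the UMIs per cell of the positive cells, values were ICRE contrast ribosomal proteins -0.049 and -0.072. With an ICRE call at 2 UMIs, values were ICRE contrast ribosomal proteins -0.22 (spleen).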

Other observations

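These values were chosen after the data were seen, and no explanation of them was tested.

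Myc differed across clusters that the report takes as 1 class. Within the resting Treg-like class, cluster 5 held 6.85 CPM in lymph node (9 UMIs) and 16.2 CPM in spleen (interval 11.3 to 22.6), against 16.9 and 29.8 CPM in cluster 1. Cluster 4, led by Lrrc32 and Il2ra, held 57.6 and 61.5 CPM although about equal ICRE and Foxp3 UMIs were seen there, and cluster 0, with few ICRE UMIs, held 37.9 and 45.3 CPM. The unnamed cluster 2, whose leading genes include Srm and Hspd1, held 52.8 and 51.2 CPM.

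Effector Treg-like cells differed between the tissues in homing and suppressor genes. Lymph node homing genes were higher in lymph node in 12 of 13 members (median 0.46, percentile 100), and suppressor effectors were lower in 14 of 15 (median -0.48, percentile 0). Some of these genes are markers of the class. Mitochondrially encoded genes, which also follow RNA quality, were higher in lymph node effector cells in 10 of 12 members (median 0.15, percentile 99.3).

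The unnamed cluster 11 was led by Cxcr6, Zbtb16 and T cell receptor gamma constant genes and held 90 lymph node and 138 spleen cells, with 2 and 7 Foxp3 UMIs and no ICRE UMI.

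ICRE-positive Treg-like cells held fewer UMIs than ICRE-negative ones when ICRE was called on all UMIs, with medians of 1538 against 2000 in lymph node and 1555 against 1792 in spleen. Within cluster 5 the medians were 1495 against 1493 and 1465 against 1476, within cluster 1 they were 1519 against 1766 and 1568 against 1889.5, and within cluster 4 they were 1546 against 1667 and 1625 against 1700. Spleen cluster 0, with 12 positive cells, had 3047 against 2680.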
